A study of Mus musculus with 2 samples.

How the data were processed

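Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against H3K27me3, the trimethylated lysine 27 of histone H3 that the Polycomb complex PRC2 deposits, was made on mouse hindbrain at embryonic day 14.5. The 2 biological replicates were separate pools of tissue, from 24 and 34 embryos of both sexes, per the labels. Replicate 2 combined 2 technical replicates. Both replicates form 1 group, so no comparison between conditions was possible, and every comparison was made between peak lists, genes or chromosomes within this tissue.

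The authors deposited 4 lists of peaks in the narrowPeak format on the mouse assembly mm10 (GRCm38). Per the file headers, each replicate's list came from that replicate's alignments and its own control, the pooled list came from both replicates and both controls together, and the replicated list was derived from those 3 lists. The peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. The signal value of each peak, a measure of its enrichment, was deposited by the authors. It was used only to describe, rank or filter peaks within a list and to correlate overlapping peaks of the 2 replicates. The −log10 p and −log10 q of each peak were likewise deposited by the authors, and the lowest −log10 p was 2.01 in replicate 1 and 2.06 in replicate 2. A peak list holds no read counts, so the sequencing depth is unknown and no interval for counting error was computed. A region outside a peak was not called, which is not the same as lacking the mark. The narrowPeak format records compact enrichment, whereas H3K27me3 forms broad domains, so a single domain was often split into many peaks.

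Genes were taken from GENCODE M21, which uses the same assembly. Of its 21951 protein-coding genes, 21755 on chromosomes 1 to 19 and X were used and 196 on Y and the mitochondrial genome were left out. A promoter was the window of 1000 bp either side of the gene's annotated 5′ end, and it was called marked when a peak touched at least 1 bp of it. Peak cover was the percentage of a window that lay in peaks, taken over 5000 bp either side of the 5′ end (the 10 kb window), or, for Hox genes, over the gene body plus 1000 bp upstream. A promoter was called CpG-rich when its CpG observed/expected ratio was at least 0.6 and its GC content at least 50%, over the GRCm38 sequence. Domains were made by joining replicated peaks within 3000 bp of each other and were ranked by the bases in peaks. Coordinates are 1-based and on mm10.

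Overlap between peak lists and the number of marked promoters were compared with 100 random placements of the peaks, each peak kept on its chromosome with its length, as a one-sided permutation test whose smallest p is 0.0099. Promoters marked in a gene list were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. The same exact test compared CpG classes, the X chromosome with autosomes, and forebrain with hindbrain regulators. Differences of mean peak cover were tested with 100000 resamples in a two-sided permutation test. Each of these tests runs across genes, which are not independent replicates, since neighbours share domains. The replicated list was the main list, and each replicate's own list was run beside it.

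The 19 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the protein-coding genes whose 5′ end lies in the 10 largest domains, the 2 members of each list with the most and up to 2 with the least peak cover in the 10 kb window, every exception where 3 or fewer members of a list go against the rest, all Hox genes, the Polycomb and cell cycle genes Ezh2, Eed, Suz12, Cdkn2a and Cdkn2b, and the 5 pooled peaks of highest signal value that the replicated list lacks. Further genes are named as examples of a list or of a strong peak, and these were chosen after their values were seen.

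The functions were tested on simulated data before use. For the promoters marked, peaks planted at 200 of 21755 gene 5′ ends were all recovered, and the 235 genes marked equalled the count from bedtools. For the replicate overlap, the simulated lists gave a Jaccard index of 0.327 both here and with bedtools. For the gene lists, 2.8% of random lists had an exact p under 0.05. This rate need not hold for lists of neighbouring genes, which share domains. For the Hox comparison of 39 genes, 85.0% of simulated differences of 20 percentage points passed the permutation test, as did 2.8% of draws without a difference. The difference later found in the replicated list was smaller, at -13.5, so the 85.0% does not give the power for it. The compared Hox sets differed in spread (SD 19.2 in the less covered and 5.28 in the more covered set), and neighbouring genes share domains. The simulated rates therefore need not hold for the Hox test.

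The alternatives tried were the pooled list, each replicate's list alone, a q-value of at most 0.01, the upper 50% of the list by signal value, promoter windows of 500 and 2500 bp, at least 50% of the window covered, 10000 random gene lists matched on CpG content, other overlap rules and other gaps between peaks. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and bedtools 2.31.1 served for the checks. No column of the files was left without a sample or group.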

Results

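H3K27me3 was profiled by ChIP-seq in the hindbrain of mouse embryos at day 14.5, the stage at which the cerebellum and the nuclei of the pons and medulla are forming. The mark is laid down by the Polycomb complex PRC2 and is known from silenced developmental genes. Whole tissue was used and expression was not measured, so a peak does not say in which cells a gene was marked or silent. The data are 1 group of 2 biological replicates, each a pool of embryos of both sexes. Replicate 1 had 51898 peaks over 21.9 Mb (0.833% of the genome) and replicate 2 had 61132 peaks over 29.1 Mb (1.10%). The replicated list, on which the comparisons rest, had 24850 peaks over 26.1 Mb (0.992%). Its peaks had a median length of 608 bp and reached 49351 bp. Since the files hold no read counts, the depth of each replicate is unknown. Values of single genes are given for the replicated list, with each replicate's own value beside some of them.

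The largest H3K27me3 domains lay over the Hox clusters, the gene arrays that set position along the body axis. When peaks within 3000 bp were joined, 8870 domains resulted, of which 461 held at least 10 kb of peaks and together 40.9% of the covered bases. The first was the whole Hoxc cluster on chromosome 15 (102894444 to 103071941), with 169.5 kb in peaks (150.2 kb in replicate 1 and 157.7 kb in replicate 2). Hoxa2 to Hoxa13 with Evx1 on chromosome 6 (52162892 to 52328824) had 146.2 kb, Hoxb1 to Hoxb9 on chromosome 11 (96245833 to 96378966) had 116.6 kb, and the Hoxd cluster with Evx2 on chromosome 2 (74639396 to 74766890) had 116.2 kb. The Hoxa domain also held the 5′ ends of the annotated genes 5730596B20Rik and Gm28308, and the Hoxd domain that of Gm28230. Rank 3 fell to a domain of 130.4 kb on chromosome 7 (49613917 to 49761151) over Dbx1, a homeobox gene of ventral neural progenitors, that reached the 5′ end of Htatip2.

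Of the remaining domains among the 10 largest, 2 lay on the X chromosome and 3 on other chromosomes. Nkx2-1, a regulator of the ventral forebrain and thyroid, lay in a domain with 95.8 kb of peaks on chromosome 12 (56435396 to 56546200). Olig2, which drives oligodendrocyte and motor neuron formation, lay in a domain with 82.4 kb on chromosome 16 (91155737 to 91248406). On the X chromosome, a domain with 98.8 kb over Iqsec2 (152111313 to 152231214) and another with 90.8 kb over Cdx4, Chic1, Tsx and Gm26992 (103310749 to 103452312) were among the 10. The domain of rank 10, with 75.5 kb on chromosome 4 (117347962 to 117445569), held no protein-coding 5′ end and lay within the gene Rnf220. The ranking has no test, and the 10 kb mark was set after the plan. With a gap of 1000 bp in place of 3000 bp, the 10 largest domains touched 6 of these 10.

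All 39 Hox genes were marked at the promoter in the replicated list and in each replicate, against 13.8% of other genes (Fisher's exact test, adjusted p = 3.06e-33). Over all clusters together, the genes of paralog groups 1 to 5 were less covered than those of groups 6 to 13. The former lie at the 3′ end and are expressed furthest forward. Mean cover of the gene and 1000 bp upstream was 83.0% ± 19.2 (SD, n = 15 genes) in the first set and 96.5% ± 5.28 (SD, n = 24 genes) in the second, a difference of -13.5 percentage points (permutation p = 0.00016). The difference was -14.4 in replicate 1 (permutation p = 0.0097) and -18.0 in replicate 2 (permutation p = 3.0e-05). The test shuffled genes across all clusters, which hold unequal shares of the 2 sets, so cluster and paralog group are not separated. Hoxa2, which patterns the second branchial arch and the rostral hindbrain, was the least covered Hox gene at 20.97% (21.4% and 14.8% in replicates 1 and 2). Hoxa5 followed at 69.0% (61.6% and 70.5%) and Hoxb2 at 74.1% (47.2% and 63.5%). The annotated span of Hoxc5 runs over Hoxc6, Hoxc8, Hoxc9 and part of Hoxc10, and that of Hoxa3 over Hoxa6, so their values in part measure the other set. In alternatives chosen after the data were seen, the difference was -14.8 without Hoxa3 and Hoxc5 (permutation p = 0.0001) and -9.03 without Hoxa2 (permutation p = 0.00034).

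**Figure D1:**
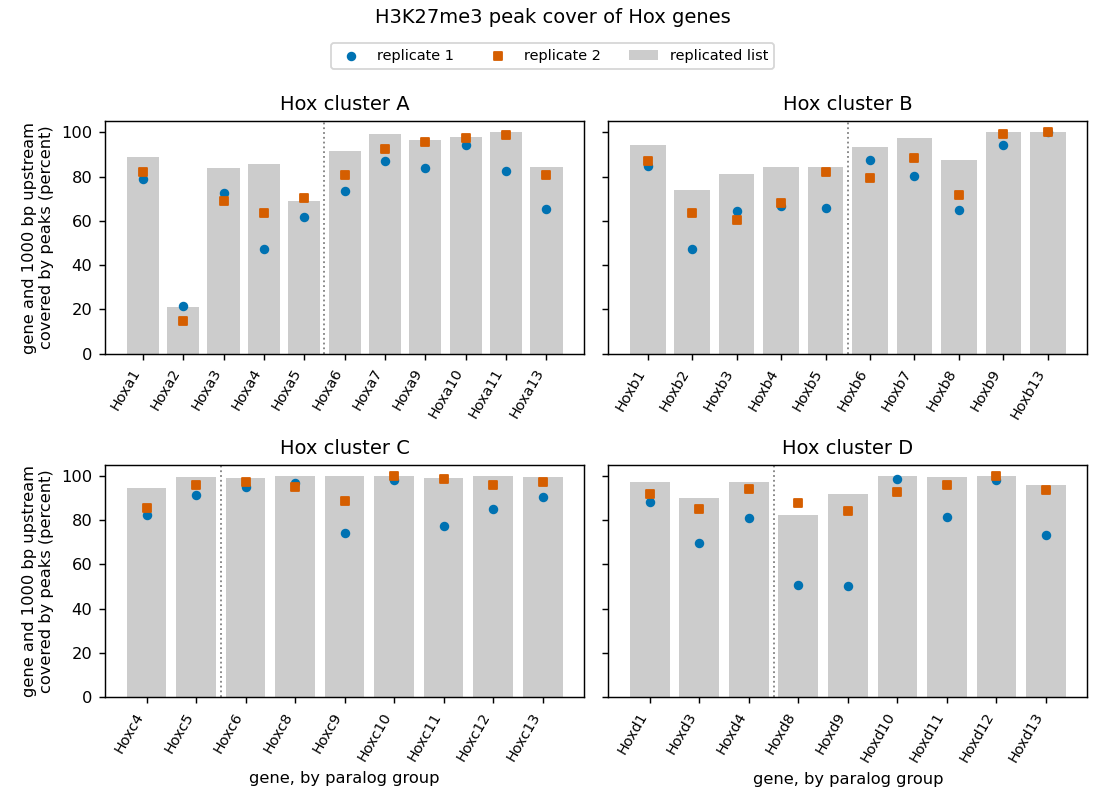
Percentage of each Hox gene and its 1000 bp upstream covered by H3K27me3 peaks, by cluster, with genes in the order of their paralog groups and a dotted line between groups 5 and 6. Bars are the replicated list and points are the 2 replicates' own lists; Hoxa2 has the shortest bar, at 20.97%.

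The contrast was widest in clusters A and B. In cluster A, the 5 genes of the 3′ set had a mean cover of 69.7% ± 28.3 (SD) and the 6 genes of the 5′ set 95.01% ± 6.02. Hoxa1 (88.9%), Hoxa3 (83.8%) and Hoxa4 (85.6%, with 47.1% and 63.5% in replicates 1 and 2) stood between Hoxa2 and the far end of the cluster, where Hoxa6 had 91.7%, Hoxa7 99.3%, Hoxa9 96.7%, Hoxa10 98.1% and Hoxa11 100%, with Hoxa13 lower at 84.3%. In cluster B the means were 83.7% ± 7.31 (n = 5 genes) and 95.8% ± 5.27 (n = 5 genes). Hoxb1 had 94.4%, Hoxb3 81.4%, Hoxb4 84.2% and Hoxb5 84.3%, while Hoxb6 had 93.5%, Hoxb7 97.6%, Hoxb8 87.6%, and Hoxb9 and Hoxb13 100%. In cluster C of the replicated list, Hoxc4 had 94.6% (82.2% and 85.3% in replicates 1 and 2), Hoxc5 99.7%, Hoxc6 98.9%, Hoxc11 99.1% (77.3% and 98.7%) and Hoxc13 99.5%. Hoxc8, Hoxc9 (74.2% and 88.6%), Hoxc10 and Hoxc12 (84.9% and 95.9%) were at 100%. In cluster D the 3′ genes Hoxd1 (97.2%), Hoxd3 (89.9%) and Hoxd4 (97.1%) averaged 94.7% ± 4.20 and the 5′ genes 94.8% ± 7.01 (n = 6 genes). In replicate 1 the order in cluster D was the reverse of that over all clusters, with means of 79.6% for the 3′ and 75.4% for the 5′ genes, and in replicate 2 they were 90.3% and 92.4%. Hoxd8 had 82.2% (50.5% and 87.9% in replicates 1 and 2), Hoxd9 91.6% (50.2% and 84.4%), Hoxd11 99.3% and Hoxd13 95.8%, and Hoxd10 and Hoxd12 were at 100%. Differences within single clusters were not tested.

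**Figure D2:**
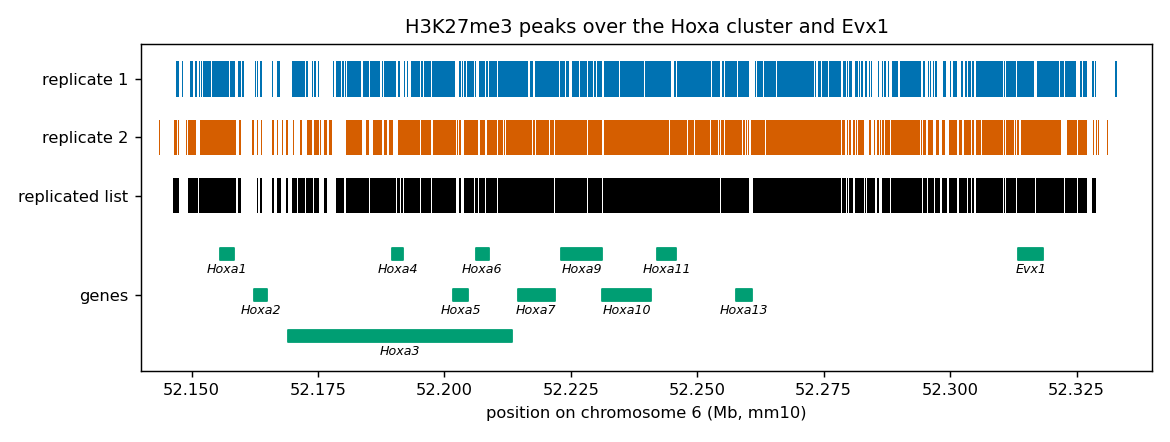
Map of the Hoxa cluster and Evx1 on chromosome 6 (mm10, position in Mb), with the peaks of replicate 1, replicate 2 and the replicated list as bars and the genes below. Peaks are sparse around Hoxa2 and nearly continuous from Hoxa7 to Hoxa11.

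Transcription factors of other brain regions and germ layers were marked almost as completely as the Hox genes. Among 30 regulators of forebrain and midbrain, 28 had a marked promoter (93.3%, Fisher's exact adjusted p = 1.95e-21), and the count was 28 in replicate 1 and 29 in replicate 2. Otx1 and Six3, which specify the anterior brain, were covered over 100% of the 10 kb window in the replicated list, at 88.1% and 98.3% in replicate 1 and 89.1% and 98.2% in replicate 2. Foxg1, the telencephalic regulator, had 85.9%, Emx2 90.2% and Tbr1 62.6% (37.4% and 63.4% in replicates 1 and 2). The 2 exceptions were Bcl11b, with 14.4% of the window covered (2.82% and 18.82%) and a promoter marked only in replicate 2, and Hesx1, with no cover in the replicated list.

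Mesoderm and endoderm regulators showed the same picture. Of 30 mesoderm factors, 26 were marked (adjusted exact p = 2.42e-18), with T (Brachyury), the regulator of early mesoderm, at 100% of the window and Tbx3, a limb and heart factor, at 99.1%. The heart genes Hand2 (94.2%) and Nkx2-5 (93.5%) were also covered. The 4 unmarked members were Msgn1 and the myogenic factors Myf5, Myf6 and Myog, each with no cover in the replicated list although the Myf6 promoter was marked in replicate 1, whereas Myod1, of the same myogenic family, had 69.6%. Of 18 endoderm factors, 16 were marked (adjusted exact p = 6.02e-12), led by Foxa2 (100%) and the intestinal regulator Cdx2 (99.6%). The exceptions were the liver factors Hnf1a (11.99% of the window, outside the promoter) and Hnf4a (no cover).

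Signalling ligands and genes of the neural crest followed. Of 43 Wnt, Bmp, Fgf and Hedgehog ligands, 34 were marked (79.1%, adjusted exact p = 4.77e-21), with Wnt6 at 97.4% and Wnt10b at 97.1% of the window. Shh, secreted by the floor plate, had 82.7% and Fgf8, a signal of the midbrain-hindbrain boundary, had 90.6%, while Bmp5 and Bmp10 had no cover. Among 13 neural crest and peripheral nerve genes, 10 were marked (adjusted exact p = 1.22e-06). Prdm12 (97.5%), needed for pain-sensing neurons, and Tfap2a (95.7%) had the most cover. The 3 exceptions were Dbh and Th, enzymes of catecholamine synthesis, and the myelin gene Mpz, all without cover in the replicated list, although the Th promoter was marked in replicate 1.

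Lists of glia, vessels, meninges and blood were marked in part. Among 13 glial genes 6 were marked (adjusted exact p = 0.0082): the factors Olig2 (96.2%), Nkx2-2 (95.6%), Olig1 (93.1%) and Sox10 (41.4%), the receptor Pdgfra (89.3%) and the myelin gene Mbp (13.3%, with 4.33% and 13.3% in replicates 1 and 2), while Aqp4, Aldh1l1, Plp1 and Mog had no cover. Among 14 endothelial genes 8 were marked (adjusted exact p = 0.0004), with Sox7 at 84.6% and Fli1 at 84.0%, whereas Cdh5 and Emcn had none. Of 16 genes of meninges and mesenchyme, 8 were marked (adjusted exact p = 0.0012), with Foxc1 at 89.4% (54.9% and 87.3%) and Foxc2 at 85.6%, against no cover at Acta2 and Col3a1. In the blood and microglia list, 5 of 18 were marked (adjusted exact p = 0.12, not past the threshold): Gfi1 (94.95%), Tal1 (86.2%), Ikzf1 (54.9%, with 32.3% and 54.0% in replicates 1 and 2), Lyl1 (48.9%) and Klf1 (15.1%, with 8.86% and 18.7%). The microglial genes Aif1 and Cd68 had no cover.

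Of 18 neural progenitor genes 8 were marked (44.4% against 13.9% of other genes, adjusted exact p = 0.0029). Pax6, the progenitor factor, had 98.9% of its window covered (89.0% in replicate 1 and 93.4% in replicate 2) and Sox1 74.0%, while Fabp7, a radial glia protein, and the Notch ligand Dll1 had none in the replicated list. With at least 50% of the promoter window required, this list no longer passed (exact adjusted p = 0.21). Of 18 pan-neuronal genes only 2, the neurofilament gene Nefl (29.0%, with 12.8% and 36.3% in replicates 1 and 2) and Ina (9.56%), were marked (adjusted exact p = 1), and Dcx and Elavl3 had no cover. None of 25 housekeeping genes was marked, Actb and Cct2 included (adjusted exact p = 0.059), although in replicate 2's own list, also with none marked, the adjusted exact p was 0.022. None of 20 germ cell genes was marked either, Dazl and Ddx4 among them (adjusted exact p = 0.12).

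**Figure D3:**
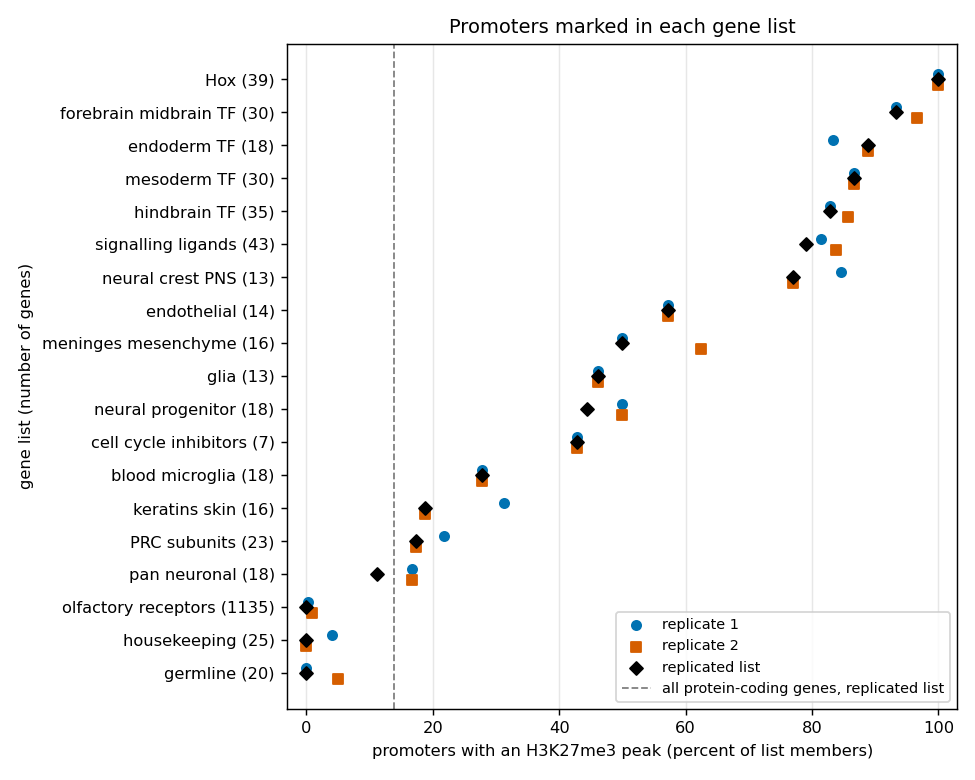
Percentage of promoters with an H3K27me3 peak in each of the 19 gene lists, with the number of genes in parentheses; circles, squares and diamonds are replicate 1, replicate 2 and the replicated list. The dashed line is the 13.9% of all protein-coding genes, and points run from 0% in germ cell genes to 100% in Hox genes.

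Olfactory receptor genes were the only list with fewer marked promoters than the rest that passed the test, with 0 of 1135 marked against 14.7% of other genes (adjusted exact p = 3.23e-75), 3 in replicate 1 and 10 in replicate 2. Their promoters are poor in CpG. Against random lists matched on CpG, with 1.91% marked on average, the difference was -1.91 in place of -14.7 percentage points (permutation adjusted p = 0.00047). The matched lists were drawn from all genes, the olfactory receptors included, which lowers their marked share. How much of the smaller difference is due to CpG can therefore not be told. Among 16 keratin and skin genes 3 were marked (adjusted exact p = 0.54), namely Grhl3 (56.6%, with 34.2% and 46.8% in replicates 1 and 2), Grhl1 (36.6%, with 21.8% and 35.4%) and Lor (13.3%, with 7.26% and 21.2%), while Flg and Ivl had no cover. Among 23 Polycomb subunits 4 were marked (adjusted exact p = 0.58): Cbx8 (79.6%), Cbx4 (52.9%), Pcgf1 (49.6%) and Phf19 (20.7%). The Cbx8 promoter was marked in replicate 1 and not in replicate 2. The PRC2 core genes Ezh2, Eed and Suz12 had no peak within the window in any of the 4 lists, nor did Cbx6 and Aebp2. Of 7 cyclin-dependent kinase inhibitors, 3 were marked (adjusted exact p = 0.083): Cdkn2b (98.8%), Cdkn2a (96.9%) and Cdkn2c (44.8%). Cdkn2a and Cdkn2b, a known Polycomb target locus, lay in a single domain with 48.7 kb of peaks on chromosome 4 (89265362 to 89316056), and Cdkn1a and Cdkn2d had no cover in the replicated list.

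Regulators of the hindbrain itself were also widely marked, but over less of their surroundings than those of the forebrain and midbrain. Of 35 hindbrain factors 29 were marked (82.9%, adjusted exact p = 3.40e-19), which did not differ from the 28 of 30 forebrain and midbrain factors (Fisher's exact p = 0.27). Mean cover of the 10 kb window was 66.3% ± 30.6 (SD, n = 35 genes) for hindbrain and 84.9% ± 23.2 (SD, n = 30 genes) for forebrain and midbrain regulators, a difference of 18.6 percentage points (permutation p = 0.0075). It was 19.003 in replicate 1 (permutation p = 0.0026) and 19.8 in replicate 2 (permutation p = 0.0025). Neurog1 and Olig3, proneural and dorsal progenitor factors, were covered over 100% of the window, and Ptf1a, required for inhibitory cerebellar neurons, over 97.0%. Atoh1, the factor of the granule cell lineage, had 73.6%, En1 83.4%, En2 80.4% and Pax2 74.4%. Whether these genes were silent, and in which cells of the tissue, was not measured. The 6 members unmarked in the replicated list were Meis1, Nfib and Pbx3, each with no cover, Meis2 (8.45%, with 8.61% and 4.31% in replicates 1 and 2), Nfia (18.4%, with 6.47% and 17.9%) and Zic1 (49.9%, with 32.9% and 54.0%). The Zic1 promoter was marked in each replicate's own list and that of Nfib in replicate 2. The reverse held for Ascl1, a proneural factor with 14.9% of its window covered, whose promoter was marked in the replicated list and in neither replicate's own.

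Over all genes, 3028 of 21755 promoters (13.9%) were marked, 4.90 times the mean of 618 ± 27.02 (SD) in 100 random placements, whose maximum was 698 (permutation p = 0.0099, the smallest they can give). The ratio was lower in the lists not filtered for replication, 3.17 in replicate 1, 3.04 in replicate 2 and 2.74 in the pooled list, and 11.9 with at least 50% of the window covered. Replicate 1 marked 3246 promoters, replicate 2 marked 3673, and 2808 were marked in both. The peak of highest signal value, 18.3, covered Klf14 on chromosome 6 (30956135 to 30962941). It was followed by peaks at Otx1 (15.8), Pax9 (14.5), Evx2 (14.0) and Hoxb13 (13.2). Of the replicated peaks, 17.4% touched a promoter, 39.3% lay in a gene body and 43.3% were intergenic. These shares count peaks and cannot be set directly against shares of the genome. By bases, 13.4% of the replicated peaks lay in promoter windows, which make up 1.56% of the genome. Gene bodies and promoter windows together make up 40.05% of the genome, and no enrichment in gene bodies was tested. With at least 50% of the window covered required, 1736 promoters were marked.

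CpG-rich promoters, which include those of Pax6, Otx1 and Cdx2, were marked more often than the others. Of 6531 CpG-rich promoters 17.8% were marked, against 12.3% of the other 15224, an odds ratio of 1.55 (Fisher's exact p = 1.76e-26). The odds ratio was 1.37 in each replicate's own list. CpG-rich promoters were 38.4% of the marked ones, and such strongly covered genes as Six3, Nkx2-1 and Olig3 fell in the other class under the definition used.

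X-linked promoters were marked in 14.6% of 948 genes and autosomal ones in 13.9% of 20807, a difference that did not pass the test in the replicated list (Fisher's exact p = 0.56). In the replicates' own lists the X share was higher, 17.7% against 14.8% in replicate 1 (exact p = 0.015) and 20.1% against 16.7% in replicate 2 (exact p = 0.0068). With at least 50% of the window covered required, X lay 2.39 percentage points below the autosomes, a difference of -2.39 (exact p = 0.0069). Counting all peaks, promoter peaks included, the X chromosome stood apart, with 31.8 replicated peaks per Mb against at most 13.9 on an autosome (chromosome 19), and 53.9 and 67.6 in replicates 1 and 2 against 31.1 and 34.6 on chromosome 19. Replicated peaks covered 2.10% of X and 1.80% of chromosome 19. Large X domains beyond those over Iqsec2 and Cdx4 lay at Zfx (70.6 kb), at Fam90a1b and Apoo (68.5 kb) and at Slc16a2 (2 domains, of 66.6 and 60.7 kb). In the same order they held 46.4, 44.1, 46.2 and 42.6 kb of replicate 1's peaks. Replicate 2's peaks covered 62.5, 55.9, 54.6 and 50.5 kb of them.

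**Figure D4:**
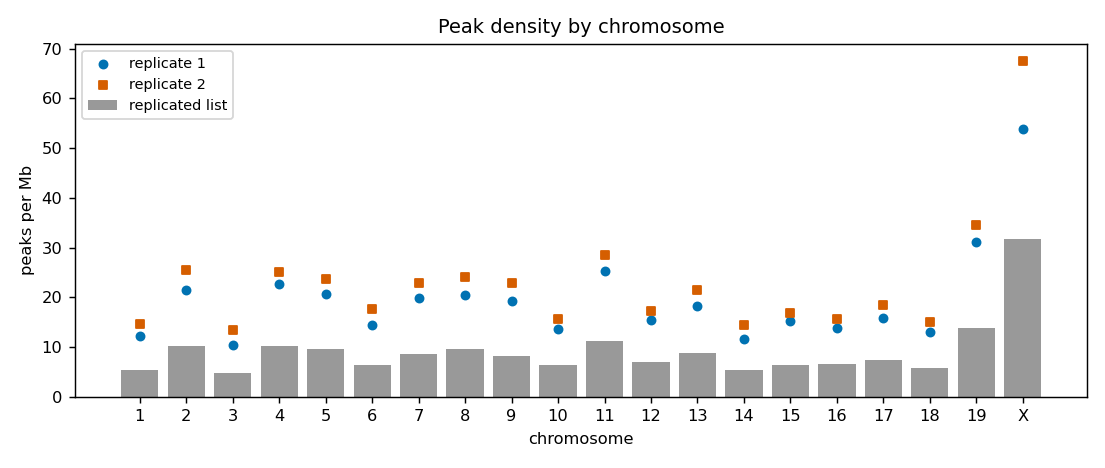
Number of H3K27me3 peaks per Mb on each chromosome; bars are the replicated list and points are the 2 replicates' own lists. The X chromosome is highest in all 3, with 31.8 peaks per Mb in the replicated list.

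The replicates shared most of their strongest peaks and fewer of the others. Of replicate 1's peaks 54.8% (28457) were touched by a peak of replicate 2, and 39.99% (24446) of replicate 2's by a peak of replicate 1. Random placement gave 2.43% and 1.81% (permutation p = 0.0099 for both, the smallest 100 placements can give). The Jaccard index of covered bases was 0.355, against a mean of 0.00546 in the placements. In the highest 10% by signal value 97.2% of replicate 1's and 92.1% of replicate 2's peaks were shared, and in the lowest 10% 45.1% and 28.2%. The share did not rise evenly in between, and its lowest values, 34.8% and 18.01%, lay above the lowest 10%. Each shared replicate 1 peak was paired with the replicate 2 peak that overlapped it most, so some replicate 2 peaks recur. Over the 28457 pairs of overlapping peaks the authors' signal values had a Spearman rho of 0.36 and, on the log2 scale, a Pearson r of 0.416. These are correlations across peaks within 1 pair of replicates, and peaks are not independent.

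The replicated list kept 24850 of the 76164 pooled peaks (32.6%), each with unchanged coordinates, and these held 65.0% of the pooled bases. Kept peaks had a median signal value of 3.65 and a median length of 608 bp, against 2.67 and 242 bp for the others. Of the kept peaks 75.4% were touched by both replicates' lists and 290 by neither, while 403 peaks that were not kept were touched by both. The 5 strongest pooled peaks left out had signal values from 4.67 to 5.49. They lay on chromosome 4 near 6430628N08Rik (115890222 to 115890542), on chromosome 17 at Mpig6b and Ly6g6c (35065068 to 35065969) and at H2-K2 (33977148 to 33977484), on chromosome 13 in Rad17 (100618341 to 100618638) and on chromosome 16 in Eaf2 (36827118 to 36827413).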

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

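The alternatives from the plan and those added later (pooled peaks touched by both replicates, a CpG class over 500 bp, lists without X-linked genes, CpG-rich regulators only and Hox genes without Hoxa2 or without Hoxa3 and Hoxc5, all chosen after seeing the data) were compared with the results above. The CpG, Hox and forebrain-hindbrain comparisons and the replicate overlap kept their direction and their side of the threshold in each alternative run. The difference in X promoters, 0.667 percentage points in the replicated list, passed the test at 5.32 with the pooled list and at 2.93 to 3.41 when either replicate was left out. It reversed to -1.10 in the upper 50% by signal value, not past the threshold (Fisher's exact p = 0.30). With at least 50% of the window covered it was -2.39 (Fisher's exact p = 0.0069). The cause was not tested. That window rule also left 1736 marked promoters in place of 3028, as fewer windows can meet it. The Spearman rho between replicates moved from 0.36 to 0.453 with −log10 p and to 0.395 with an overlap of at least 50%. The share of pooled peaks kept rose to 43.2% (43.25%) among those with a q-value of at most 0.01. Ranked by span, 763 domains reached 10 kb in place of 461.

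Of 209 alternatives over the 19 gene lists 194 kept direction and side of the threshold. The pan-neuronal list, below the background by 2.81 points, lay 8.71 points above it with the pooled list and 1.75 above it without replicate 2 (-0.217 without replicate 1), and the Polycomb subunits went to -2.76 points with a window of 500 bp and to -7.99 with 50% of the window covered, none past the threshold. Housekeeping and germ cell genes passed when lists matched on CpG were the background (permutation adjusted p = 0.025 and 0.030) and with a window of 2500 bp, germ cell genes also with the pooled list and housekeeping genes without replicate 1. Cyclin-dependent kinase inhibitors passed in 4 alternatives, and neural progenitor genes were lost with 50% of the window covered. The cause was not tested. No paired analysis was possible because there is only 1 group. The depth is unknown, and a missing peak cannot be read as missing mark.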

Other observations

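The gene families and the summary of X windows below were chosen after their values were seen, as were the prediction for shared peaks by signal value and the choice of the 3 peaks weighed for repeated words. The other predictions were written after the pattern and before their own test was run. Genes outside the 19 lists were grouped by the stem of their symbol, which gave 245 families of at least 10 genes. After adjustment over the families 13 were marked more often than other unlisted genes and 9 less often by Fisher's exact test. Among 14 serotonin receptor genes (stem Htr) 11 were marked, with Htr1a, Htr2c and Htr7 among them and Htr2b, Htr3a and Htr3b the exceptions (exact adjusted p = 4.17e-06). Both replicates' own lists gave similar counts, 11 and 12. The 14 two-pore-domain potassium channel genes (stem Kcnk) also had 11 marked members, Kcnk3 and Kcnk9 included, with 9 in replicate 1 and 10 in replicate 2. Of 42 genes with the stem Col, nearly all collagens, 22 were marked (52.4%, exact adjusted p = 2.99e-07), among them Col2a1, Col4a1 and Col4a2. Of 10 Frizzled receptors 7 were marked, with Fzd1, Fzd3 and Fzd8 the exceptions, and of 10 adenylate cyclase genes 6 were marked.

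Other families had few or no marked promoters in the replicated list. None of 331 vomeronasal receptor genes (stem Vmn, exact adjusted p = 1.34e-19), 67 histone genes (stem Hist), 50 ribosomal protein genes (stem Rpl) or 42 beta-defensin genes (stem Defb) had a marked promoter, although 2 vomeronasal genes did in replicate 2. Of 394 zinc finger genes with the stem Zfp, 15 were marked (3.81%, with 18 and 23 in replicates 1 and 2, exact adjusted p = 5.10e-09), and Zfp503, Zfp36l1 and Zfp488 were among them. Many members of these families lie side by side and are not independent.

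The density of peaks on the X chromosome, 2.29 times that of the next chromosome, was weighed first. This ratio counts peaks, whereas the share of bases in peaks was 2.10% on X and 1.80% on chromosome 19. If weak calls near the threshold made the high density, it should vanish among stronger peaks. In the upper 50% of the list by signal value the ratio was 2.02. That part begins at the list's median signal value, 3.65, so it can still hold weak calls and does not exclude them. If the 10 largest X domains made the high density, it should vanish without them, but the ratio was 2.03. Domains end at gaps of 3000 bp, and leaving these out only lowered X from 31.8 to 28.2 peaks per Mb. Concentration in wider regions of X was therefore not tested by this step and is described below. Peaks spread evenly along the whole chromosome, as predicted for a mark along an inactive X, were argued against. Of the 1 Mb windows of X, 33.3% held more peaks than the median autosomal window, against 45.0% of autosomal windows. No peak lay in 57.3% of X windows, against 33.8% of autosomal ones. This speaks of called peaks alone, so a regional or diffuse mark on an inactive X was not tested and stays open, as do differences between the control and the ChIP on X, since the labels give pools of both sexes and no single-sex sample was analysed here.

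The 17 densest of the 171 X windows held 77.04% of X peaks, against 52.9% of autosomal peaks in the 245 densest of 2454 autosomal windows. Most of these 17 X windows adjoined, in runs at 102000001 to 106000000, 140000001 to 143000000, 160000001 to 163000000 and 166000001 to 170000000. The called peaks of X were thus concentrated in wider regions, and the median X window held 0 peaks, against 3 for autosomes. The window with the most, 377, was 103000001 to 104000000, with Cdx4, Chic1, Tsx, Slc16a2 and Rlim. The next held 356 peaks (167000001 to 168000000, with Tlr7 and Tlr8), and that with Iqsec2, Smc1a and Kdm5c held 313. X peaks were shorter than autosomal ones, with median lengths of 520 and 643 bp, and peaks of at least 2 kb were rarer on X, at 0.772 per Mb against 2.02 on chromosome 19. Of X peaks 3.77% touched a promoter, against 21.2% of autosomal peaks.

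Among the 20 replicated peaks with the highest −log10 p, 17 had signal values of at least 10.05 and 3 did not. The first of these, in Cdk8 on chromosome 5 (146261001 to 146261482), had the highest −log10 p of the list, 120.5, with a signal value of 6.49. The others, on chromosome 17 (39847865 to 39848915 and 39843006 to 39846794, at Gm42418, AY036118 and Gm26917), had signal values of 2.39 and 2.31. A candidate explanation is sequence present in further copies, whose reads pile up in both ChIP and control. The share of 31-base words found elsewhere in the assembly was at least 5.88% in these 3 peaks and had a median of 2.01% in the other 17, although it reached 9.83% in the peak near Cdkn2a. The 2 peaks on chromosome 17 lie at the same locus and are not independent, so no test is given. Copies missing from the assembly were not counted, and no biological explanation was tested.

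For peaks found in 1 replicate only, weak calls near the threshold are a candidate explanation, since 97.2% of the highest 10% of replicate 1's peaks by signal value were shared and 45.1% of the lowest, although the share fell to 34.8% between them and so did not rise evenly with signal value. Edges or fragments of domains found in both replicates are another candidate. Of the 23441 unshared peaks of replicate 1, 63.1% lay within 3000 bp of a replicate 2 peak. At most 8.96% did in 100 random placements (permutation p = 0.0099, the smallest they can give). This took all replicate 2 peaks, shared or not, and random placement ignores the clustering of peaks, so it cannot decide. With peaks within 3000 bp merged, 41.5% of replicate 1's and 32.8% of replicate 2's were shared, against 54.8% and 39.99% unmerged. Merging also changes the number of peaks counted. The Jaccard index went the other way, from 0.355 unmerged to 0.493 merged, with the joined gaps counted as covered. The explanations do not exclude each other, and a difference in depth or in the 2 controls stays open because no read counts were analysed here.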
